A study of Rattus norvegicus with 8 samples.

How the data were processed

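Total RNA was profiled from rat brain cells sorted by flow cytometry for the markers A2B5 and OTMP at postnatal day 7. Each of 4 biological replicates was read on 2 Affymetrix array types, named chip A and chip B in the labels, which gave 8 samples in 2 groups of 4. The labels describe these cells as purified A2B5/OTMP+ perineuronal oligodendrocytes, the oligodendrocytes that lie against neuronal cell bodies. There was 1 cell population and no control group. The number of animals behind a replicate is not given in the sources used here, so the p-values concern these replicates only. Those of limma rest on a variance pooled in part across probe sets, more so on chip B.

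RNA was extracted with a Qiagen kit and labelled with biotin by Affymetrix's protocol for small samples, per the labels' protocols. RMA, which corrects background, quantile-normalizes and summarizes probe sets, was the processing tool per the submitters' processing notes, with no version. The values deposited by the authors are linear ratios of a probe set's signal to a reference that no label names. They were not log2 intensities, which is the scale RMA usually gives. The values point to a per-probe-set median over a larger set of arrays that included these. On chip B, 23.0% of probe sets held the value 1 exactly on at least 1 array, against 1.26% for 0.99 and 0.691% for 1.01. On chip A, 5.22% of probe sets had a pair of arrays averaging 1 within 0.0005, against 1.42% for 0.98 and 0.936% for 1.02. The series text names an earlier oligodendrocyte dataset for comparison, which was not used here, and whether its arrays formed the reference is not given in the sources used here. The identity of the reference, its number of arrays and any floor set on the values stay unknown. The lowest deposited ratio was 0.01 and the highest 34.3. A ratio places a gene against this reference. It gives neither the gene's brightness nor whether the gene was expressed, and it cannot rank one gene's expression above another's.

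Ratios were put on the log2 scale. The median ratio per array was 0.903, 0.93, 0.946 and 0.907 on chip A and 0.887, 0.905, 0.967 and 0.963 on chip B for replicates 1 to 4 in order. Centring the arrays on these medians raised log2 ratios by 0.12 on chip A and 0.10 on chip B on average. Control probe sets were left out of the tests, 57 on each array type, which left 15866 on chip A and 15276 on chip B. Genes were named from the platform's annotation. On chip A 12783 probe sets had 1 gene symbol, 312 had several and 2771 had none, and on chip B the counts were 7564, 100 and 7612. The gene IDs of 12754 and 7530 single-gene probe sets were in the RefSeq gene table for assembly GRCr8, which led to 0 updated symbols. No gene was named from a probe set with several symbols. Gpr17, which was due to be named, had no single-gene probe set and has no value here, and 1 other item is not reported here.

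The main test was planned for log2 levels and asked which probe sets stood above background. Because the values are ratios, the same test asks which probe sets had a higher ratio than genes not expected in brain cells. The gene lists, the tests and the rule for named genes were chosen before the data were examined. The panel of genes from other organs (protamines, digestive enzymes, milk proteins, liver enzymes and the like) held 97 probe sets on chip A and 7 on chip B. Its 95th percentile on each array, called the panel level, was subtracted. Chip B had fewer than 20 panel probe sets, so its level was that of the same-numbered chip A array plus the median difference over the 157 probe sets present on both types. This shared set included control probe sets and held 100 without them. The panel level lay at a ratio of 1.16, 1.39, 1.35 and 1.11 on chip A and 1.07, 1.34, 1.32 and 1.06 on chip B. The log2 excess was tested with limma (an intercept and eBayes, one-sided), with Benjamini-Hochberg adjustment within an array type at 0.05. Two-sided limma tests against a ratio of 1, and one-sided tests below the panel's 5th percentile, were added after the values were seen. In those against 1, a gene counted as higher or lower if any of its single-gene probe sets did, and separately if it had probe sets of both kinds.

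A gene counted as above the panel level if any of its single-gene probe sets did, and it is reported by the probe set with the largest mean excess. This choice raises the values of genes with several probe sets. An alternative used each gene's median probe set. For an even number of probe sets it took the lower of the middle pair, so for a gene with a single pair the lower probe set decided. There were 20 lists: OPC and oligodendrocyte lineage (OPC, oligodendrocyte precursor cell), myelin and mature oligodendrocyte, neuron, astrocyte, microglia and macrophage, endothelial cell, mural cell and fibroblast, ependyma and choroid plexus, erythroid, cell cycle, proteoglycans and perineuronal matrix, growth factor receptors, glutamate receptors, receptors for GABA, glycine, acetylcholine and purines, glycolysis and lactate, cholesterol synthesis, ganglioside synthesis, cytoskeleton and microtubule proteins, stress and immediate early genes, and housekeeping genes. Each list was compared with all other named genes by Fisher's exact test, two-sided, adjusted over the lists. Genes are not independent replicates, so this test describes these arrays. The position of a list's median excess over the panel level was given as a percentile among 10000 random lists of the same size, while medians in the text are of the log2 ratio itself. Camera, limma's set test, was run on chip A with an estimated correlation between genes; it asks whether a list's mean differs from that of other genes. Its direction was up for the myelin, erythroid, cell cycle and glycolysis lists, whose medians were below 0.

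The named genes were a fixed set of lineage, cell type and matrix genes, from each list the 3 with the largest and the 2 with the smallest mean excess, and per array type the 10 single-gene probe sets with the highest mean. A further part of the rule, the most variable probe sets among those called more variable, named none because none was called. Variation between replicates was tested with limma's trended, robust prior. Whether equal replicate numbers on the 2 array types mark the same RNA was tested by an exact permutation test over the 24 matchings. The array types were normalized separately. No gene's level was compared between them, though the panel level of chip B was carried over from chip A through the shared probe sets.

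The limma tests were tested on simulated data. With 50 probe sets raised by 1, 2 or 3 log2 units each, 100% were recovered on chip A at each size, and 98%, 100% and 100% on chip B. At 0.5 units the shares were 36% and 44%. The raised probe sets were drawn at random and kept their own moderated SD. In the data, probe sets called above a ratio of 1 varied more, with a median SD of 0.28 and 0.32, against 0.21 and 0.19 over all. These shares therefore do not hold for genes with a wide spread. Ntrk3, for instance, had an excess of 1.59 (SD 1.21) and was not called. Unchanged probe sets made up 3.45% of the calls in the chip A simulation and 12.8% in that of chip B, where limma borrowed more strongly across probe sets (17.1 prior degrees of freedom against 3.52). With a trended, robust prior the shares were 1.96% and 3.25%. Alternatives covered the panel level, the threshold, a minimum size, the normalization, the variance prior, the choice of probe set, the array type and leaving out each replicate. The number of arrays limits the precision. The analysis used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.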

Results

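Perineuronal oligodendrocytes were isolated from the brain of 7-day-old rats by flow cytometry for A2B5, a ganglioside epitope of glial precursors, and for OTMP, the other marker of the sort. RNA from 4 biological replicates was hybridized to 2 array types, chip A with 15866 tested probe sets and chip B with 15276. Every value was a ratio to an unnamed reference for that probe set, so a high value means more signal than in the reference, not a bright gene. Across probe sets, pairs of replicates correlated with r from 0.716 to 0.792 on chip A and from 0.710 to 0.786 on chip B. Values below are mean log2 ratios ± SD over the 4 arrays of a type (n = 4), with adjusted p-values from limma. With 1 cell population in the series, the question was which genes and gene groups stood out from the reference, measured against a panel of genes not expected in brain cells.

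Genes with the highest ratios on chip A included Plcd4, a phospholipase C, at 3.70 ± 0.33 (limma adjusted p = 0.000182), the potassium channel gene Kcnd2 at 3.39 ± 0.76 (0.00273), the adenylyl cyclase gene Adcy8 at 3.37 ± 0.48 (0.00123) and the mitochondrial carrier gene Slc25a34 at 3.37 ± 0.38 (0.000857). Shisa9, an AMPA receptor auxiliary subunit gene, stood at 3.20 ± 0.47 (0.00164), Myorg, an astrocyte glycosidase gene, at 3.17 ± 0.43 (0.00145), and Agt, which encodes angiotensinogen and is made by astrocytes in brain, at 2.98 ± 0.23 (0.000602). Only 1 of the 4 Myorg probe sets lay above the panel level, and the lowest stood at -0.85. The other 3 of the 10 highest probe sets named by 1 gene varied more between replicates: the organic anion transporter gene Slco1a5 at 3.48 ± 1.61 (0.0284), Mfrp at 3.25 ± 1.42 (0.0264) and the calcium pump gene Atp2b3 at 3.03 ± 1.24 (0.0214). These 3 calls were lost without replicate 2 (limma adjusted p = 0.136, 0.139 and 0.124) and without replicate 4 (0.111, 0.084 and 0.0757). All 3 had their lowest ratios in replicate 3, at 2.41, 2.56 and 2.48. The lowest of the 3 Atp2b3 probe sets stood at -0.68.

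On chip B the transcription factor gene Etv4, a target of fibroblast growth factor signalling, was highest among probe sets named by 1 gene, at 3.69 ± 0.17 (limma adjusted p = 1.08e-11). Next came the ferritin receptor gene Scara5 at 2.78 ± 0.66 (3.84e-08), the integrin gene Itgb6 at 2.59 ± 1.18 (7.2e-06), Slc35d3 at 2.37 ± 0.25 (2.87e-08) and the ephrin receptor gene Ephb3 at 2.36 ± 0.25 (2.87e-08). The other Ephb3 probe set stood at -0.006. Egfl6 stood at 2.23 ± 0.32, the citrate transporter gene Slc13a5 at 2.22 ± 0.08, the GABA-A receptor subunit gene Gabra2 at 2.15 ± 0.87 and the neuronal adhesion gene Ntm at 2.07 ± 0.35, with limma adjusted p from 2.4e-07 to 4.03e-08 except 1.13e-05 for Gabra2. With a trended, robust prior these chip B genes had larger limma adjusted p-values, from 0.000231 for Etv4 to 0.0182 for Ntm. The neurexin gene Nrxn3 reached 2.28 ± 1.80, with ratios of 16.4, 10.5, 1.02 and 3.21 in replicates 1 to 4. Its call above the panel level (limma adjusted p = 0.00136) was lost without replicate 4 (0.1), and it did not pass against a ratio of 1 (0.0832). The p-values above the panel level on chip B drew largely on the pooled variance (17.1 prior degrees of freedom). They therefore do not carry the wide spread of Itgb6 and Nrxn3 in full.

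In total 379 of 15866 probe sets on chip A (2.39%) and 553 of 15276 on chip B (3.62%) lay above the panel level by limma, against 953 and 1049 at an unadjusted p under 0.05. Of these, 285 and 166 were named by 1 gene. Counted by gene, 265 passed on chip A and 161 on chip B, the latter with the panel gene Slc22a8. On either type 413 of 13728 named genes outside the panel passed (3.01%). Mean ratios of the called probe sets ran from 1.71 to 13 with a median of 2.83 on chip A, and from 1.68 to 15 with a median of 2.28 on chip B. Of the panel's own probe sets, 0 of 97 on chip A passed in limma (0 at an unadjusted p under 0.05), and 1 of 7 on chip B did (Slc22a8, 0.89). On chip A the level was set near the top of these same 97 probe sets. Almost none could pass by construction, so that outcome is no check of the test. The chip B level was carried over from chip A, but 7 probe sets are too few to give a rate. The chip B count is the less certain, since it was 73 with a trended, robust prior, where that of chip A was 200. Without replicate 4 the counts were 203 and 280, with 196 and 267 probe sets shared with the full set. Of the 45 called probe sets that the rule for named genes picked, 19 were lost with the panel's maximum as the level (limma adjusted p from 0.0749 to 1): Bcan, Cspg5, Dpysl5, Egfl6, Elavl4, Gabra2, Gfap, Gria2, Hapln1, Hes5, Ntm, Ntrk2, Pdgfrb, Pfkm, Ptprz1, Reln, Slc13a5, Tnc and Ttr.

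Against a ratio of 1, more probe sets were lower than higher: 4768 below and 1462 above on chip A (23.5% of calls above), and 4142 and 776 on chip B (15.8%). By the same calls on chip A, 49.5% of panel probe sets were lower, against 30.8% of other named ones. After centring each array on its median, which added 0.12 and 0.10 to the log2 ratios, the counts were 3689 below and 1878 above on chip A (33.7%) and 3614 and 875 on chip B (19.5%). Below the panel's 5th percentile lay 86 and 61 probe sets in limma. With any 1 replicate left out this was 0 on chip A (199 to 212 at an unadjusted p under 0.05) and 0 to 24 on chip B (144 to 174). Some bacterial control probe sets had low and even ratios too. A thr control on chip A had 0.388, 0.417, 0.413 and 0.382 in replicates 1 to 4, and another ran from 0.915 to 1.01. A low, even ratio, such as those of several genes named below, therefore does not by itself show that a gene was less expressed.

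**Figure D1:**
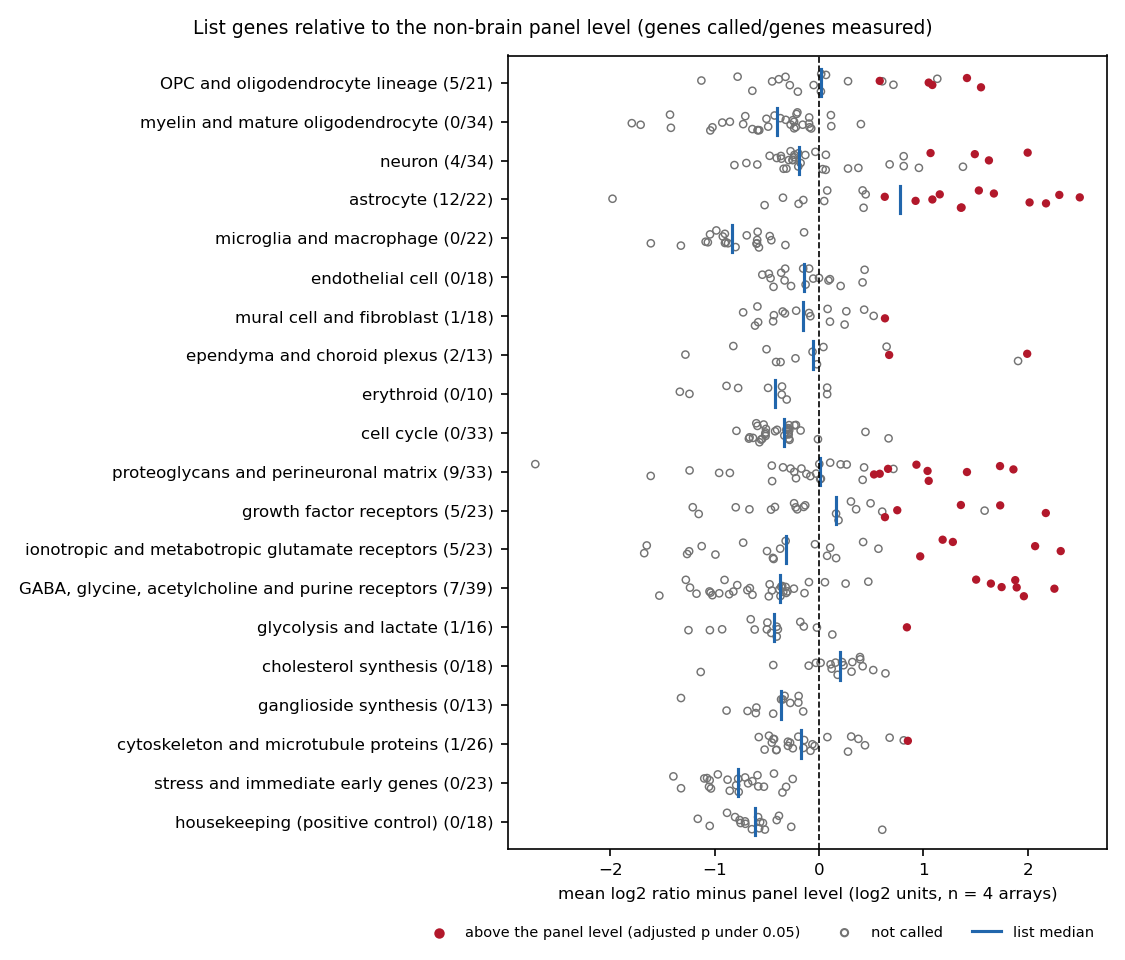
Each point is 1 gene of a list, placed at its mean log2 ratio minus the panel level over 4 arrays (log2 units); filled points lay above the panel level (limma adjusted p under 0.05), open points did not, and bars mark list medians. The astrocyte list holds 12 filled points of 22 genes, while the microglia, endothelial, myelin and cholesterol lists hold 0.

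Astrocyte genes stood out most. Of 22 measured, 12 lay above the panel level: the water channel gene Aqp4 at 2.82 ± 1.28 (limma adjusted p = 0.0297), the bicarbonate transporter gene Slc4a4 at 2.62 ± 0.58 (0.00376), the folate enzyme gene Aldh1l1 at 2.50 ± 0.52 (0.00191), and Gfap, the intermediate filament of astrocytes, at 1.41 ± 0.20 (0.00292). The others were Aldoc, Clu, Fgfr3, Mlc1, Ntsr2, Plpp3 and the glutamate transporters Slc1a2 and Slc1a3. The list's median log2 ratio was 1.10, above all 10000 random lists (percentile 100). By Fisher's exact test 54.5% of the list against 2.93% of other genes were above (odds ratio 39.8, adjusted p = 4.62e-12), and 15 genes passed when adjusted over the list alone. With an estimated correlation, camera did not set the list's mean apart from that of other genes (adjusted p = 0.323). With the preset correlation it did (camera adjusted p = 1.3e-09). Several genes of the list were not above the panel level, among them the vimentin gene Vim at -0.20 ± 0.30. Another was the transcription factor gene Sox9 at -1.73 ± 0.01, below a ratio of 1 (limma adjusted p = 5.93e-05). The only Sox9 probe set held ratios of 0.299 to 0.304, and ratios cannot tell whether it detected the transcript. Aqp4 ranged from a ratio of 3.04 in replicate 4 to 23.3 in replicate 1, and its call was lost without replicate 2 (limma adjusted p = 0.089).

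Genes of the oligodendrocyte lineage list divided. Bcan (brevican) at 1.37 ± 0.25 (limma adjusted p = 0.00976), Cspg5 (neuroglycan C) at 1.74 ± 0.16 (0.00145), the Notch target Hes5 at 1.87 ± 0.36 (0.00396), the receptor phosphatase gene Ptprz1 at 0.90 ± 0.19 (0.0483) and Sox11 lay above the panel level, 5 of 21 measured. The lineage transcription factor genes lay near the reference: Olig1 at -0.07 ± 0.50, Olig2 at -0.03 ± 0.03, Sox10 at 0.00 ± 1.15 and Nkx2-2 at -0.39 ± 0.40, none past either test. Sox10 ranged from a ratio of 0.401 in replicate 2 to 2.57 in replicate 4. The precursor receptor gene Pdgfra at 0.93 ± 0.65 was above a ratio of 1 (limma adjusted p = 0.0362) and not above the panel level (0.558), except without replicate 2 (0.0488). Cspg4, which encodes NG2, stood at 0.34 ± 0.60, Id4 at 1.45 ± 0.77 (limma adjusted p = 0.141), and the lowest members were C1ql1 at -0.88 ± 1.07 and Lhfpl3 at -0.53 ± 0.68. The list passed Fisher's exact test (23.8% against 2.98%, odds ratio 10.2, adjusted p = 0.00164, with 7 genes when adjusted over the list alone). In camera it had adjusted p = 0.496 with an estimated correlation and 1.03e-05 with the preset one. In Fisher's exact test the list no longer passed with a trended, robust prior (adjusted p = 0.0761) or with each gene's median probe set (0.171). Bcan, Hes5 and Ptprz1 had a pair of probe sets each, of which the latter setting took the lower, at 0.71, -0.01 and 0.86. With the panel's maximum as the level it had 0 genes. Of its genes 7 also belong to another list, and the called Bcan, Cspg5 and Ptprz1 are in the proteoglycan list. Olig1, Olig2, Sox10, Nkx2-2, Pdgfra and Cspg4 were not called, so the enrichment does not rest on them. Whether the called genes' signal came from lineage cells or from other cells was not tested.

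Proteoglycans and perineuronal matrix genes overlapped with that group. Above the panel level were 9 of 33: the link protein gene Hapln1 at 2.18 ± 0.75 (limma adjusted p = 0.0111), the tenascin gene Tnc at 2.06 ± 0.27 (0.00211), Bcan, Cspg5, Ptprz1, the glypicans Gpc2, Gpc4 and Gpc6, and the syndecan Sdc4. Vcan (versican) stood at 1.03 ± 0.50 without passing (0.166), except without replicate 2 (0.0265), and Tnr (tenascin R) at -0.13 ± 1.34. Ncan (neurocan) at -0.92 ± 0.29 lay below a ratio of 1 (limma adjusted p = 0.00303), as did the chondroitin sulfotransferase genes Chst3 at -1.29 ± 0.07 (0.000123) and Chst11 at -2.47 ± 0.02 (5.93e-05). The Chst3 ratios of 0.389 to 0.429 were close to those of a bacterial thr control on chip A (0.382 to 0.417). Ratios cannot tell whether the Chst3 and Chst11 probe sets detected their transcripts. The list's share was 27.3% against 2.95% (Fisher's exact test, odds ratio 12.3, adjusted p = 3.76e-06, with 11 genes when adjusted over the list alone). In camera the list had adjusted p = 0.666 with an estimated correlation and 8.45e-05 with the preset one. With a trended, robust prior 3 of its genes passed (adjusted p = 0.0257), and with the panel's maximum as the level 0 did. The call of Hapln1 was lost without replicate 4 (2.16, limma adjusted p = 0.0548) and that of Ptprz1 without replicate 1 (0.84, 0.162), 3 (0.85, 0.0908) or 4 (0.96, 0.166). Their means stayed close to those of all 4 arrays. With the trended, robust prior Ptprz1 (limma adjusted p = 0.338) and Bcan (0.0545) did not pass.

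Myelin genes did not stand out. None of 34 lay above the panel level by limma (0 when adjusted over the list alone, and 0 at an unadjusted p under 0.05). The myelin basic protein gene Mbp stood at 0.08 ± 0.13, Cnp at 0.05 ± 0.20, Mog at 0.22 ± 0.33, Mag at 0.43 ± 0.36, Mobp at 0.10 ± 0.36, Cldn11 at 0.16 ± 0.15 (other probe set -1.41), Cntn2 at 0.72 ± 0.58 and Gsn at 0.44 ± 0.50. Against a ratio of 1, 13 had a lower probe set and 0 a higher one, among them the connexin gene Gjb1 at -1.39 ± 0.08 (limma adjusted p = 0.000117) and the aspartoacylase gene Aspa at -1.48 ± 0.29 (0.000547), while against the array median 7 were lower, 1 was higher and 1 had probe sets of both kinds. The list's median was -0.11, at percentile 31.3 of random lists (Fisher's exact test adjusted p = 0.963; camera adjusted p = 0.986), but its place was unsettled, at 0.77 without replicate 4 and 98.2 on chip A alone.

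**Figure D2:**
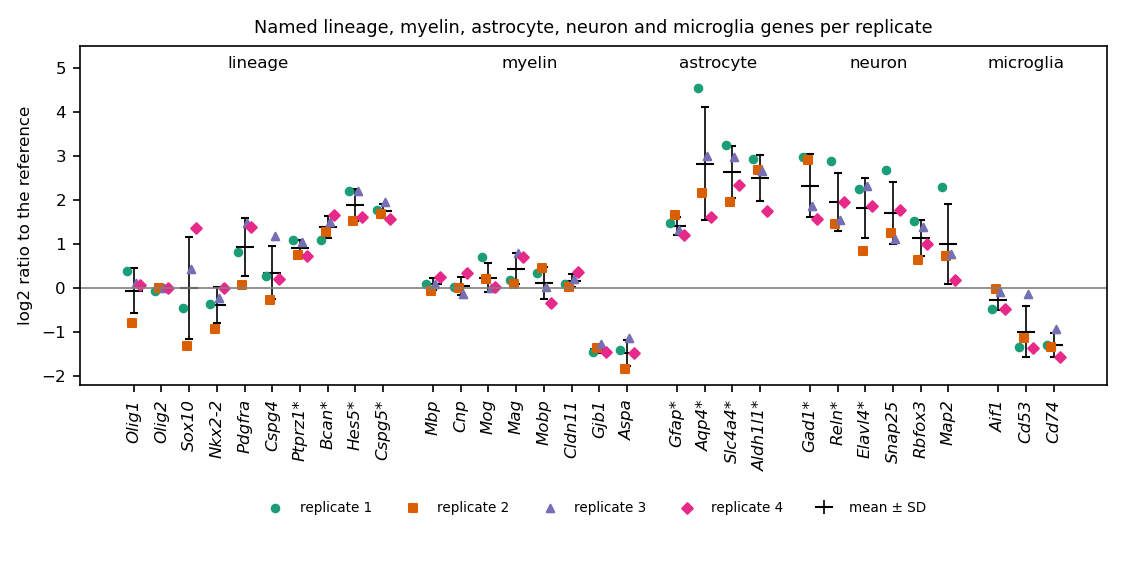
Log2 ratio of named genes on each array (points, 1 per replicate) with the mean and SD of 4 replicates. Stars mark genes above the panel level; Gfap and Cspg5 lie above 0 on all 4 arrays, and Sox10 lies on both sides of it.

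Receptor genes were the other groups with more calls than other genes. Among growth factor receptors 5 of 23 lay above the panel level: the epidermal growth factor receptor gene Egfr at 2.49 ± 0.44 (limma adjusted p = 0.00272), the neurotrophin receptor gene Ntrk2 at 2.06 ± 0.49 (0.00678), Erbb2, Fgfr3 and Pdgfrb. Only 1 of the 5 Ntrk2 probe sets lay above the panel level, and the lowest stood at 0.50. Ntrk3 at 1.91 ± 1.21 did not pass (0.158), except without replicate 2 (0.0109), and the neuregulin receptor gene Erbb3 at -0.83 ± 0.06 (0.000364) and Met at -0.89 ± 0.08 (0.000337) lay below a ratio of 1. The list passed Fisher's exact test (21.7% against 2.98%, odds ratio 9.05, adjusted p = 0.00172, with 7 genes when adjusted over the list alone). In camera it had adjusted p = 0.666 with an estimated correlation and 0.0109 with the preset one. In Fisher's exact test the list no longer passed with a trended, robust prior (adjusted p = 0.0775) or with median probe sets (0.173). It also did not pass with the panel's maximum as the level (1 gene, 0.347) or on chip A alone (0.0524).

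Glutamate receptor genes went both ways. The NMDA receptor subunit genes Grin2c at 2.64 ± 0.35 (limma adjusted p = 0.00172) and Grin3a, the metabotropic receptor gene Grm3 at 2.39 ± 0.53 (0.00217), the AMPA receptor subunit gene Gria2 at 1.60 ± 0.34 (0.00941) and the kainate receptor subunit gene Grik5 made up the 5 of 23 above the panel level. Against a ratio of 1, 11 genes had only lower calls, such as Grm5 at -1.33 ± 0.10 (limma adjusted p = 0.000134) and Grm7 at -1.36 ± 0.07 (0.000113), 6 had only higher calls and 1 had both. Lower calls were common on chip A as a whole, at 49.5% of panel probe sets and 30.8% of other named ones. Fisher's exact test gave adjusted p = 0.00172 (odds ratio 9.05; 5 genes when adjusted over the list alone), while the list's median was 0.00 (percentile 79.3, or 99.8 without replicate 2) and camera gave adjusted p = 0.957 with an estimated correlation.

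Receptor genes for GABA, glycine, acetylcholine and purines also went both ways. Of 39 genes 7 lay above the panel level, of which 6 were GABA receptor subunits, led by Gabbr2 at 2.58 ± 0.30 (limma adjusted p = 0.00147), Gabrb2 at 2.28 ± 1.12 (0.0465) and Gabra2 at 2.15 ± 0.87 (1.13e-05). The 7th was the adenosine receptor gene Adora2b. The other probe set of Gabbr2 stood at -1.32 and that of Gabrb2 at -1.06. Against a ratio of 1, 20 genes had only lower calls, such as the muscarinic receptor gene Chrm1 at -1.21 ± 0.06 (limma adjusted p = 0.000134) and Gabra4 at -0.96 ± 0.13 (0.000437), 5 had only higher calls and 3 had both. With 49.5% of panel probe sets and 30.8% of other named ones lower on chip A, lower calls are not particular to these receptors. Fisher's exact test gave adjusted p = 0.000945 (odds ratio 7.15; 8 genes when adjusted over the list alone), and camera adjusted p = 0.957 with an estimated correlation. The list's median was -0.05, at percentile 50.4 of random lists, or 0.05 with each gene's median probe set, and Gabrb2 was lost without replicate 4 (limma adjusted p = 0.133) and with a trended, robust prior (0.0528). The list no longer passed with bacterial controls as the level (5 genes, Fisher's exact test adjusted p = 0.127), with the panel's maximum (2 genes, 0.0684) or against a ratio of 1 (0.0576).

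Neuronal genes included some high ratios. The glutamate decarboxylase gene Gad1 stood at 2.32 ± 0.72 (limma adjusted p = 0.00762), the secreted matrix protein gene Reln at 1.95 ± 0.65 (0.0238), the RNA-binding protein gene Elavl4 at 1.81 ± 0.68 (0.0312), and the vesicular glutamate transporter gene Slc17a6 was the other call among 34 measured. The synaptic gene Snap25 at 1.70 ± 0.70 (limma adjusted p = 0.0537) and the neuronal nuclear antigen gene Rbfox3 at 1.13 ± 0.41 (0.0725) did not pass, though both lay above a ratio of 1 (0.00577 and 0.00399). Snap25 passed without replicate 1 (limma adjusted p = 0.0206) or 3 (0.00759), and Rbfox3 without replicate 2 (0.0247). The dendritic microtubule gene Map2 at 1.0 ± 0.91 did not pass (0.732), and its ratio was 4.92 in replicate 1 and 1.14 to 1.71 in the others. Syt1 at -0.45 ± 0.03 (limma adjusted p = 0.00127) and Neurod6 at -0.56 ± 0.13 (0.00334) lay below a ratio of 1, where 8 genes of the list had only higher calls, 5 only lower ones and 2 both. The list fell short in Fisher's exact test (11.8% against 2.99%, odds ratio 4.33, adjusted p = 0.0524, with 7 genes when adjusted over the list alone). In camera it had adjusted p = 0.251 with an estimated correlation and 1.55e-05 with the preset one. By Fisher's exact test the list passed in 11 of 16 alternatives. Among them were a trended, robust prior (adjusted p = 0.0257), without replicate 1 (0.00551) and without replicate 3 (0.0245). Gad1 was lost without replicate 2 (limma adjusted p = 0.0508), Reln without replicate 2 (0.0516) or 4 (0.0986), and Elavl4 without replicate 4 (0.124). The other probe set of Gad1 stood at -0.97.

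Cytoskeleton and microtubule genes gave 1 call of 26, Dpysl5, a collapsin response mediator, at 1.17 ± 0.07 (limma adjusted p = 0.00895, or 0.0901 with a trended, robust prior). Stmn2 stood at 1.13 ± 0.44 (0.104) and Dpysl2 at -0.26 ± 0.18. The list's median of 0.15 lay at percentile 99.7 of random lists, or 93.8 without replicate 1. Fisher's exact test gave adjusted p = 0.963, and 1 gene passed when adjusted over the list alone. Camera gave adjusted p = 0.666, or 0.00715 with the preset correlation.

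Markers of vascular, choroid plexus, immune and blood cells were measured because a sort can carry other cells. Choroid plexus genes varied between replicates: the water channel gene Aqp1 at 2.32 ± 1.16 (limma adjusted p = 0.0454) and the transthyretin gene Ttr at 0.99 ± 0.20 (0.033) lay above the panel level, and the homeobox gene Otx2 at 2.23 ± 1.46 did not (0.139). All 3 were lowest in replicate 3, at ratios of 1.75, 1.66 and 1.05, and the rest ran up to 12.4 for Aqp1 and 9.77 for Otx2. Slco1a5, Mfrp and Atp2b3 of the highest genes on chip A, and Itgb6 on chip B (1.94), were lowest there as well. The ependyma and choroid plexus list had 2 calls of 13 (Fisher's exact test adjusted p = 0.141; camera adjusted p = 0.882; 4 genes when adjusted over the list alone), with a median of 0.19 at percentile 99.7. This position fell to 82.6 without replicate 2, 96.8 without replicate 4 and 93.8 with median probe sets. Without replicate 3 it had 3 calls and passed (adjusted p = 0.0291), Otx2 among them (limma adjusted p = 8.45e-05). It also passed with all 4 replicates after quantile normalization (3 calls, Fisher's exact test adjusted p = 0.028). Aqp1 was lost without replicate 2 (limma adjusted p = 0.165) or 4 (0.175) and with a trended, robust prior (0.0514), and Ttr without replicate 1 (0.073), 2 (0.126) or 4 (0.127) and with that prior (0.221). The lowest members were the anti-ageing factor gene Kl at -0.96 ± 0.23 (limma adjusted p against a ratio of 1 = 0.00136) and the ciliary gene Tekt1 at -0.50 ± 0.53. The other Aqp1 probe set stood at -0.0005.

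Mural and fibroblast genes gave 1 call of 18, Pdgfrb, the pericyte growth factor receptor, at 0.88 ± 0.31 (limma adjusted p = 0.0177), which was lost without replicate 1 (0.0958), 2 (0.0987) or 4 (0.208), and with a trended, robust prior (0.945), leaving the list 0 calls. Igf2 at 0.84 ± 0.39 (limma adjusted p = 0.258) and Col1a1 at 0.75 ± 1.32 did not pass, and the list's median was 0.16 (percentile 99.3, but 60.9 without replicate 3). The lowest of the 4 Igf2 probe sets stood at -1.73. The smooth muscle genes Acta2 at -0.41 ± 0.20 (limma adjusted p = 0.0228) and Tagln at -0.29 ± 0.17 (0.0491) lay below a ratio of 1 but not below the array median (0.0527 and 0.135). Fisher's exact test gave adjusted p = 0.846, camera adjusted p = 0.939, and 1 gene passed when adjusted over the list alone.

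None of the endothelial genes passed by limma (0 of 18; 0 when adjusted over the list alone, 1 at an unadjusted p under 0.05). Slco1a4 at 0.76 ± 0.84, the angiopoietin receptor gene Tek at 0.67 ± 0.79 and Vwf at 0.53 ± 0.77 were the highest, and Pecam1 stood at -0.16 ± 0.64 and the tight junction gene Ocln at -0.22 ± 0.31. Slco1a4 and Tek passed only without replicate 1 (limma adjusted p = 0.0351 and 0.0258). Camera with the preset correlation gave the list adjusted p = 0.0366. The list's median of 0.18 lay at percentile 99.6 (Fisher's exact test adjusted p = 1; camera adjusted p = 0.938), but at 89.7, 95.8 and 95.9 without replicates 2, 3 and 4, inside the central 95%.

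Microglia and macrophage genes were low. By limma 0 of 22 lay above the panel level (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05) and 9 lay below a ratio of 1, or 3 below the array median, among them the leukocyte gene Cd53 at -1.0 ± 0.58 (limma adjusted p = 0.0193) and the antigen presentation gene Cd74 at -1.29 ± 0.27 (0.00071). Aif1, which encodes the microglial protein Iba1, stood at -0.27 ± 0.24, and Cd163 at 0.11 ± 0.41, Mrc1 at -0.07 ± 0.75 and Laptm5 at -0.21 ± 0.15 were the highest. A median of -0.52 put the list at percentile 0.01 of random lists, with Fisher's exact test adjusted p = 1 and camera adjusted p = 0.938. For the microglia list camera gave adjusted p = 0.0256 with the preset correlation. Erythroid genes had 0 calls of 10 by limma (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05), with the globin gene Hbb at 0.40 ± 0.40 and the heme synthesis genes Alas2 at 0.40 ± 0.50 and Fech at 0.01 ± 0.10. Klf1 and Rhag lay below a ratio of 1 at -0.99 ± 0.05 and -1.01 ± 0.10 (limma adjusted p = 0.000129 and 0.000281). Their median was -0.10 (percentile 33.2; Fisher's exact test adjusted p = 1; camera adjusted p = 0.986).

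Cholesterol synthesis genes lay moderately above the reference. By limma 0 of 18 lay above the panel level (0 when adjusted over the list alone, 6 at an unadjusted p under 0.05), yet 10 had only calls above a ratio of 1, 1 only below it and 2 had both, with the same counts against the array median. Tm7sf2 at 0.96 ± 0.39 (limma adjusted p against a ratio of 1 = 0.00648), the lanosterol demethylase gene Cyp51 at 0.84 ± 0.27 (0.00362) and the lanosterol synthase gene Lss at 0.74 ± 0.27 (0.00601) were the highest, Pmvk stood at -0.12 ± 0.26, and Ebp at -0.81 ± 0.40 (0.013) was the gene below. Their median was 0.52, at percentile 99.99, with Fisher's exact test adjusted p = 1 and adjusted p = 0.496 in camera with an estimated correlation. Camera gave adjusted p = 3.45e-05 with the preset correlation. With the panel's 75th percentile as the level, 7 genes passed and the list was enriched (Fisher's exact test adjusted p = 0.000619).

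Glycolysis and lactate genes gave 1 call of 16, the phosphofructokinase gene Pfkm at 1.16 ± 0.13 (limma adjusted p = 0.00447, or 0.0835 with a trended, robust prior). Adjusted over the list alone, 1 gene passed. Only 1 of the 3 Pfkm probe sets lay above the panel level, and the lowest stood at -0.06. The lactate dehydrogenase gene Ldha at -0.61 ± 0.17 (0.00403) and the hexokinase gene Hk2 at -0.93 ± 0.07 (0.000281) lay below a ratio of 1. Ldhb stood at 0.14 ± 0.19, the lactate transporter genes Slc16a1 and Slc16a7 at 0.45 ± 0.33 and -0.73 ± 0.59, and Hk1 at 0.30 ± 0.42. The other Slc16a1 probe set stood at -2.24. The glycolysis list's median was -0.11 (percentile 25.2, Fisher's exact test adjusted p = 0.846, camera adjusted p = 0.986). Ganglioside synthesis genes, which make the lipids A2B5 antibodies bind, had 0 calls of 13 by limma (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05). St8sia1, the GD3 synthase gene, lay below a ratio of 1 at -1.0 ± 0.04 (limma adjusted p = 0.000187). St8sia3, which adds further sialic acids, stood at -0.04 ± 0.05, B4galt6 at 0.17 ± 0.23, St3gal2 at 0.12 ± 0.15, B4galnt1 at 0.12 ± 0.96 and St6galnac3 at -0.57 ± 0.63. Their median was -0.08 (percentile 52.2; Fisher's exact test adjusted p = 1; camera adjusted p = 0.957).

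Cell cycle genes had 0 calls of 33 by limma (0 when adjusted over the list alone, 2 at an unadjusted p under 0.05). The G1 cyclin gene Ccnd2 stood at 0.99 ± 0.31 (limma adjusted p = 0.131), Cdc20 at 0.77 ± 0.37 (0.139), Kif11 at 0.24 ± 0.40, Rrm1 at -0.35 ± 0.33, and Pcna below a ratio of 1 at -0.47 ± 0.03 (0.0026). Ccnd2 and Cdc20 lay above a ratio of 1 (limma adjusted p = 0.00292 and 0.0128). Cdc20 also had a probe set called below it, and the lowest of its 5 stood at -0.31. Ccnd2 passed only without replicate 3 (limma adjusted p = 0.0405). The median was -0.06 (percentile 76.5; Fisher's exact test adjusted p = 0.963; camera adjusted p = 0.986). Stress and immediate early genes had 0 calls of 23 by limma (0 when adjusted over the list alone, 0 at an unadjusted p under 0.05), with Fos at 0.07 ± 0.19, Klf2 at 0.00 ± 0.06 and Egr1 at -0.03 ± 0.19 the highest, and Hspa1a at -1.0 ± 1.74 and Gadd45b at -1.08 ± 1.12 the lowest. Their median of -0.46 lay at percentile 0.02, or 3.65 without replicate 3 (Fisher's exact test adjusted p = 1, camera adjusted p = 0.938). The lowest Fos and Klf2 probe sets stood at -0.94 and -0.96. Housekeeping genes, included as a positive control for expression, had 0 calls of 18 by limma (0 when adjusted over the list alone, 1 at an unadjusted p under 0.05) and a median of -0.29 (percentile 1.66; Fisher's exact test adjusted p = 1; camera adjusted p = 0.938). The percentile was 5.02 without replicate 4, 8.73 with median probe sets and 3.68 on chip A alone. They ran from Gnas at 0.93 ± 0.42 through Rpl13a at -0.02 ± 0.03 and B2m at -0.06 ± 0.18 to Rps3 at -0.73 ± 0.21 and Rpl4 at -0.84 ± 0.65. These ubiquitous genes show that a ratio near or below 1 does not mean that a gene was silent.

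**Figure D3:**
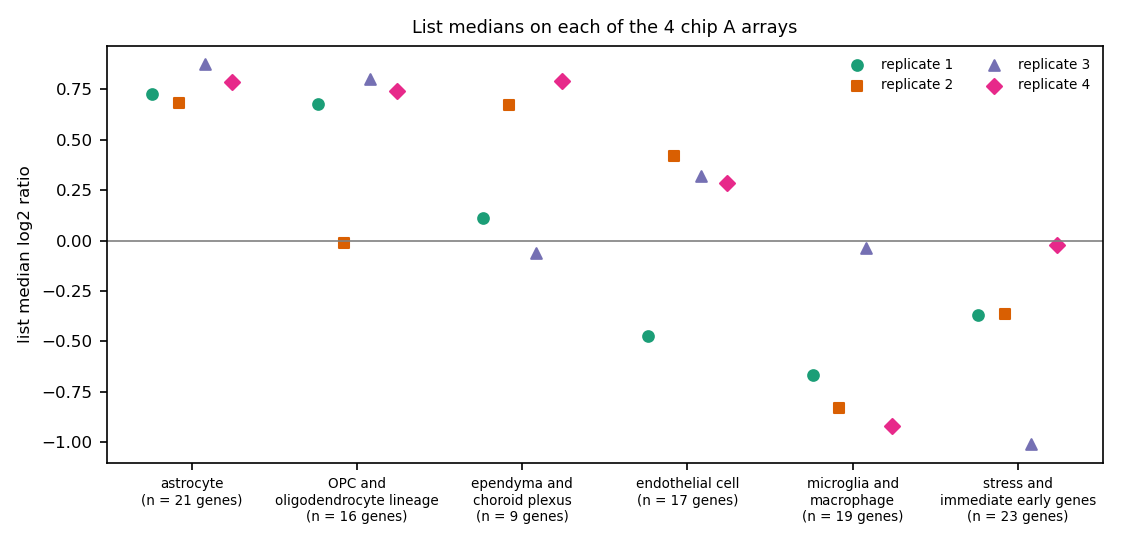
Median log2 ratio (vertical axis) over the genes of 6 lists (horizontal axis) on each chip A array, 1 point per replicate. The astrocyte list spans 0.68 to 0.87, the microglia list lies near 0 in replicate 3 alone, and the endothelial list lies below 0 in replicate 1 alone.

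Differences between replicates were followed by list. For the medians here, all chip A probe sets of a gene were averaged. The list medians given above used each gene's probe set with the largest mean excess on either type. The astrocyte median was 0.73, 0.68, 0.87 and 0.79 in replicates 1 to 4 on chip A. The lineage list had 0.68, -0.01, 0.80 and 0.74, the microglia list -0.67, -0.83, -0.04 and -0.92, and the endothelial list -0.47, 0.42, 0.32 and 0.29. Control probe sets for the 5' end of Gapdh, a sign of RNA integrity and labelling, varied on the same arrays (ratios of 0.545, 0.573, 0.991 and 0.305), those for its middle less so (0.751, 0.709, 1.04 and 0.524), and those for its 3' end ran from 0.837 to 0.975. The microglia median was highest and lowest in the same replicates as the 5' signal, and the 2 were not separated. Among the called genes of a list, 4 of 36 pairs of list and replicate fell outside the central 95% of random lists, where chance gives 1.8: the neuron list in replicates 1 (0.50 above the mean of its replicates) and 3 (-0.40), and in replicate 3 the astrocyte list (0.24) and the GABA, glycine, acetylcholine and purine receptor list (0.45). With all genes of a list, 46 of 128 pairs did, where chance gives 6.4. No single probe set was called more variable than others of its level by limma (0 on each array type, with 625 and 667 at an unadjusted p under 0.05 where chance gives 793.3 and 763.8). This test had little power, since it recovered 9% and 4% of simulated probe sets whose SD was raised 10 times. The median SD was 0.21 on chip A and 0.19 on chip B, and 102 and 161 probe sets had an SD above 1.

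The replicate numbers of the 2 array types were then compared. Over 12 genes called on both, the deviations of same-numbered arrays correlated at a mean r of 0.416 across genes, which are not independent replicates, against 0.394 for the next best of the 24 matchings (exact permutation test, one-sided, p = 0.0417, the smallest it can give). Over all 2264 genes on both types the mean r was 0.176 against 0.103.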

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

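Of the tests in this part, only the correlation test of astrocyte genes between replicates was written before its result was seen; the others were chosen after. The series holds 1 cell population, so no biological explanation was tested. A replicate far from the other 3 was sought in 176 sets of 4 values, where chance marks about 1 in 20 sets, 8.8 here, and 14 were found.

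Replicate 1 stood far above the others for Gnas (1.55 on the log2 scale, others 0.66 to 0.80) and Dpysl5 (1.28, others 1.13 to 1.14). It stood far below them for Olig2 on chip B (-0.0786, others -0.0174 to -0.0101), though by a small distance. Among list medians, replicate 1 was apart for the endothelial list (-0.47, others 0.29 to 0.42) and the cytoskeleton list (0.36, others -0.02 to 0.01) on chip A, and for the glycolysis list (-0.31, others -0.08 to -0.04) on chip B. Replicate 2 was far above for B4galnt1 (1.56, others -0.49 to -0.23), and far below for Egfr (1.84, others 2.65 to 2.80) and for the median of the oligodendrocyte lineage list (-0.0116, others 0.68 to 0.80). Replicate 3 was far below for the stress genes Hspa1a (-3.59, others -0.47 to 0.09) and Gadd45b (-2.76, others -0.56 to -0.48), and far above for Tm7sf2 (1.53, others 0.70 to 0.82). Replicate 4 was far below for Vim (-0.65, others -0.07 to -0.04) and for Slc35d3 on chip B (1.99, others 2.48 to 2.51).

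Some choroid plexus genes were low in replicate 3, seen first in Otx2 at -2.88, Aqp1 at -2.01 and the abundant Ttr at -0.35 log2 units from the mean of the others, which set the median of the 6 measured choroid plexus members at -0.43. The tables argue against a shift of the whole replicate 3 array, since the non-brain panel lay at 0.0877 (95% interval 0.0773 to 0.117) in the same comparison. Choroid plexus cells may have come through the A2B5/OTMP gate, which was set for oligodendrocytes, in varying amounts. The 3 members that had not prompted the pattern, Kl at -0.12, Folr1 at -0.52 and Kcnj13 at -0.02, had a median of -0.119, percentile 17.9 of random lists. This small set could not decide, since Kl lay below a ratio of 1 in all replicates (0.456 to 0.648) and showed no excess to lose. The explanation stays open. Only 3 of the 6 genes were lowest in replicate 3, and the 7 ependymal members of the list, at -0.78, were low too. Neither the tissue taken nor RNA integrity, with the 5' Gapdh control at a ratio of 0.991 in replicate 3 and 0.305 to 0.573 in the others, was tested as a cause.

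Astrocyte genes stood above the panel level. The choice of each gene's highest probe set is argued against as the whole cause, because with median probe sets the list still passed (Fisher's exact test adjusted p = 4.02e-08). Astrocytes passing the A2B5/OTMP gate, which was set for oligodendrocytes, are a candidate source that stays open: the 21 astrocyte genes on chip A correlated over the 4 replicates at a mean of 0.129, percentile 90.4 of random lists with a median of 0.0234, which neither meets nor excludes a share that varied between sorts. Against their own references the abundant Gfap at 1.41, Slc1a2 at 2.34 and Aqp4 at 2.82 lay above the panel level and Vim at -0.20 and Apoe at 0.40 did not, and 2 of the list's genes belong to another list. A reference with few astrocyte transcripts, or expression in the sorted cells themselves, could give the same ratios, and neither was tested.

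More probe sets lay below a ratio of 1 than above it. On chip A limma called 49.5% of the non-brain panel's probe sets below 1, against 30.8% of 12686 other named probe sets (Fisher's exact test, p = 0.000146). The panel's genes were chosen as genes not expected in brain cells. A technical difference between these arrays and those of the reference, such as in labelling or background, may therefore contribute to the low ratios. Some bacterial control probe sets on chip A were as low and even as Chst3 and Gjb1, such as a thr control at 0.388, 0.417, 0.413 and 0.382. Another thr control lay near 1 (0.915 to 1.01). Probe sets called below 1 also varied little between replicates, with a median SD of 0.11 on chip A and 0.07 on chip B, against 0.28 and 0.32 for those called above 1. These calls depend on the SD, so the selection may account for part of this difference, which decides nothing. The reference arrays were not analysed here, so how much of the pattern this accounts for stays open.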

How the results depend on the processing

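Comparisons with a ratio of 1 or the array median, tests below the panel, camera and matching on shared probe sets were chosen after seeing the data; the other alternatives were planned. Chip A's 379 probe sets above the panel level became 866 with the panel's 75th percentile, 61 with its maximum, 842 with bacterial controls as the level, 168 at an adjusted p of 0.01, 245 with an excess of at least 1, 200 with a trended, robust prior, 721 by the rule of all 4 arrays and 1462 against a ratio of 1, and ranged from 203 to 505 with 1 replicate left out. Chip B's 553 became 20 with the panel's maximum, 212 with bacterial controls, 249 with an excess of at least 1 and 73 with the trended, robust prior, and ranged from 280 to 769. Looser rules pass more probe sets by construction, and a lower level does so only where the variance estimates stay the same. With bacterial controls the chip B count fell, although each of these controls lay below the panel level on every chip B array. Otherwise the cause was not tested. The 6 enriched lists became 2 (astrocyte and glutamate receptors) with the panel's maximum. The lineage and proteoglycan lists turned to 0 genes there, and the cholesterol list turned to 7 genes with the 75th percentile, 7 with bacterial controls, 5 by the rule of all 4 arrays and 12 against a ratio of 1. The 13 lists of unusual position became 0 in camera on chip A with an estimated correlation. This turned on the correlation setting. With the preset correlation the astrocyte, lineage, neuron, proteoglycan, cholesterol, cytoskeleton, growth factor receptor, microglia and endothelial lists passed (camera adjusted p from 1.3e-09 to 0.0366). The mural, ependyma, stress and housekeeping lists did not. The 86 and 61 probe sets below the panel became 4768 and 4142 against a ratio of 1, and 0 to 0 and 0 to 24 with 1 replicate left out. The 0 probe sets more variable than others became 0 to 6 on both chips with 1 replicate left out. The 4 list deviations became 46 with all genes. Centring arrays cancels out of the tests against the panel level and of the list deviations, so it could not move them. The matching of replicate numbers held in all 3 alternatives. Of 140 named probe sets 3, 9, 1 and 12 lost and 3, 4, 3 and 0 gained their call without replicates 1, 2, 3 and 4 in order, and of 20 lists 1, 2, 3 and 3 lost their unusual position. No paired analysis was possible because the 2 groups are array types of 1 cell population, with no difference between them to test. Signal over background is unknown from ratios, so dim probe sets could not be left out.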

Other observations

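The genes in this part were chosen after their values were seen, except Sox9, and each value is a mean log2 ratio ± SD (n = 4). They stand for no pathway or group, and no set of them was tested for enrichment. The serine and glycine transporter gene Slc7a10 stood at 2.96 ± 0.11 (limma adjusted p = 0.000583), the proline dehydrogenase gene Prodh at 2.18 ± 0.18 (0.000857), the cystathionine synthase gene Cbs at 2.18 ± 0.18 (0.00132) and the glycine decarboxylase gene Gldc at 1.09 ± 0.28 (0.0424, but 0.171 with a trended, robust prior), while the glycine transporter gene Slc6a9 at 1.43 ± 0.50 did not pass (0.0527). The fatty acid ligase gene Acsl6 stood at 2.45 ± 0.30 (0.00147) and the peroxisomal transporter gene Abcd2 at 2.56 ± 0.45 (0.00206). Klf15, a glucocorticoid-responsive transcription factor gene, stood at 2.17 ± 0.18 (0.00145), and Vegfa at 2.32 ± 0.13 (0.00125).

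Other called genes were the hedgehog coreceptor gene Boc at 1.72 ± 0.35 (limma adjusted p = 0.00448), Gli2 at 1.67 ± 0.61 (0.0452, but 0.0713 with the trended, robust prior) and Gli1 on chip B at 1.42 ± 0.45 (0.000275, but 0.163). Notch1 stood at 1.26 ± 0.23 (0.0138, but 0.0786 with that prior), Pax6, a transcription factor of radial glia and astrocytes, at 1.36 ± 0.30 (0.0182, but 0.0713), the Wnt receptor gene Fzd2 at 2.30 ± 0.43 (0.00211), the BMP antagonist gene Nog at 1.89 ± 0.35 (0.00538) and the receptor tyrosine kinase gene Ret at 2.69 ± 0.48 (0.00211). Nrcam stood at 2.50 ± 0.39 (0.00145), Plxnb1 at 2.13 ± 0.18 (0.00145), Epha4 at 1.92 ± 0.41 (0.00568) and Celsr3 at 2.02 ± 0.41 (0.00765), and the potassium channel genes Kcnd3 at 2.83 ± 0.34 (0.00145) and Kcnj16 at 1.37 ± 0.21 (0.00978, but 0.0553 with the trended, robust prior).

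Some genes differed widely between replicates. The X-inactivation transcript Xist had ratios of 4.44, 0.532, 2.87 and 0.01 in replicates 1 to 4, and 0.01 was the lowest ratio on chip A. Genes of choroid plexus epithelium outside the fixed list, Cldn2 (6.29, 12.1, 1.42 and 22.5) and Htr2c (5.22, 9.21, 1.42 and 8.47), were also lowest in replicate 3. The chemokine gene Cxcl10 (0.55, 0.2, 0.0748 and 0.926) and the stress cytokine gene Gdf15 (1.07, 0.931, 0.099 and 1.31) were lowest there as well. At the other end, the galanin receptor gene Galr3 stood at -2.95 ± 0.05, with nearly equal ratios on the 4 arrays, as did Sox9 on chip B (-1.73 ± 0.01).

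Microglia genes moved together between replicates on chip A, as did endothelial genes. The mean pairwise correlation over the 4 replicates was 0.750 among microglia and macrophage genes and 0.763 among endothelial genes, both at percentile 100 of 2000 random lists, 0.438 among ependyma and choroid plexus genes (98.8), 0.262 among lineage genes (98.3) and -0.03 among neuronal genes (1.8). The 5' control probe sets of chip A moved between replicates too, at 0.545, 0.573, 0.991 and 0.305 for Gapdh and 0.685, 0.521, 0.812 and 0.494 for beta-actin, and microglia medians were highest and lowest in the same replicates 3 and 4. Endothelial medians did not follow these controls, at -0.47, 0.42, 0.32 and 0.29 in replicates 1 to 4. RNA integrity was not separated from the movement of the microglia list, and no cause was tested for any list.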
